A study of Rattus norvegicus with 14 samples.

How the data were processed

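Sperm DNA of Wistar rat males was assayed by reduced representation bisulfite sequencing (RRBS) in 14 libraries. The design text of the series speaks of RNA profiling of the amygdala instead, while sample labels and tables are of sperm RRBS, and these were followed. Per the labels' protocols, DNA was isolated with the Genomic Mini AX Swab & Semen Spin kit and libraries were prepared with the Zymo-Seq RRBS kit. Reads were processed with Trim Galore, Bismark and Bowtie on the rat assembly Rnor_6.0, per the submitters' processing notes, which give no versions. The deposited tables, 1 for each of 5 comparisons, list regions in the format of the region caller metilene, per the file headers, which do not give its settings or any coverage filter. Each table gives the methylation of every region in percent per library and per group, as deposited by the authors, on a scale of 0 to 100. The p-values and q-values in the deposited tables come from the authors' region caller: a 2-dimensional Kolmogorov-Smirnov test, a Mann-Whitney test and a q-value. In these tables the q-value equals the Kolmogorov-Smirnov p multiplied by a constant that differs by table (257191 for HFD against control, for example) and limited to 1. That test takes the CpG values of a region as observations, so it does not measure the spread between animals alone. The tables are not limited to significant regions: 98.0% of the 8555 listed regions have a q-value of 1 in the authors' deposited table, and all listed regions have at least 10 CpGs and a difference of at least 2.5 percentage points. Context (promoter, exon, intron, transcript end, intergenic) and the gene with the nearest promoter were taken as deposited. That gene can differ from the gene whose exon or intron holds the region, which is then named. The tool behind this annotation is not stated.

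Depth is unknown for every library and region, since the tables give percentages without read counts, and no interval that needs depth is given. The labels number the libraries of each group but do not state litters or animals, so p-values over libraries measure the spread between these samples. Table columns carry group codes without replicate numbers. The codes are not explained in the labels and were read as control, HFD, ELS and ELS-HFD by their letters and their 3, 4, 4 and 3 columns. At regions with identical coordinates in 2 tables, between 91.7 and 97.4% of library values were equal in the same column of both tables, and at most 0.278% in another column. The sign of each difference is the first-named group minus the second. It was checked at regions overlapping by at least 80% in tables that share a group.

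The following choices were made before the data were examined: the call threshold (a q-value under 0.05 in the authors' deposited table, since not every listed region was under a threshold), the rule for named genes, the 12 gene lists, the overlap of at least 1 bp, the list and context tests, and the alternatives of stricter q, larger difference, CpG minimum, wider overlap, sex chromosomes and gene assignment. Named genes were, per comparison, the 10 called regions with the largest increase and the 10 with the largest decrease that carry a gene name. The rule also takes the 3 genes with most called regions (no gene had more than 1), up to 4 members per list with the largest absolute difference, and up to 10 genes called in all 3 comparisons against control (there were 0). Genes outside this rule are said to be so where they are named, and a few genes that the rule takes are left unnamed. The design had assumed that no values per library would be available. The tables turned out to hold them, so means and SDs per group were computed from the library columns. The differences computed from them depart from the deposited differences by up to 2.37 percentage points in called regions, and the sign differs from the deposited one in 6 listed regions, none of them called. The limma fits, the test of the interaction, the same-direction shares of listed regions, the shares of lower regions, the Kolmogorov-Smirnov threshold and the RefSeq background for the lists, and a check of whether the libraries of the groups overlap were added after the data were seen.

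limma 3.58.1 in R 4.3.3 was run on log2((percent + 1) / (100 - percent + 1)) of the library values of all listed regions of a comparison, with Benjamini-Hochberg adjustment, and again on the percent scale. Because regions were listed for their difference, these adjusted p-values and the shares of regions without overlap are biased towards a difference. A 2 x 2 fit took 499 regions with values of all 14 libraries: 306 overlapping by at least 50% between the separation tables and 193 found so only in the diet tables. Each region takes 2 groups from each of 2 tables, so a difference between the 2 intervals falls on the diet term in the 306 and on the separation term in the 193. The fit was therefore repeated, after its result was seen, on the 162 regions with identical coordinates in both tables and on the regions where the factor is compared within a table. On simulated libraries with each region's own mean and spread and 200 shifted regions, limma recovered 21, 16, 6, 12 and 21% of shifts of 1 on the log2 odds scale for the 5 comparisons in the order HFD, ELS and ELS-HFD against control, ELS-HFD against HFD and against ELS. It recovered 69, 67, 47, 74 and 77% of shifts of 2, and beside these shifts it called 9, 7, 3, 5 and 4 unshifted regions, against 0 in runs where no region was shifted. The overlap and list functions were tested on simulated data, where 300 of 300 planted overlaps were found and 0 of 200 random lists passed.

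Overlaps of comparisons that share a group were set beside a simulation of 200000 regions without effects and beside the number of shared genes that independent lists give. All simulated regions had the median within-group SD of the listed regions, 2.86 percentage points, while SDs of real regions vary widely. Lists were tested with Fisher's exact test, two-sided, against the 3797 genes that any table names, with Benjamini-Hochberg adjustment over 60 tests. The lists cover imprinted genes, the stress hormone axis, energy balance, the glutamate and the GABA and glycine synapse, monoamine signalling, calcium and potassium channels, axon guidance, patterning transcription factors, Wnt signalling, methylation machinery, and germline genes with promoters methylated in somatic cells. Contexts were tested likewise over 25 tests. Of the 3797 genes, 2847 match a symbol in the RefSeq name table of the assembly GRCr8, which was used for names only. Genes with ribosomal, 7SK, RNase P, U6, RT1, protocadherin, LOC or AABR names belong to repeated or poorly annotated sequence, and their identity is uncertain. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. No file was left out.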

Results

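Reduced representation bisulfite sequencing reads CpG methylation at restriction fragments that are rich in CpGs. By the sample labels, sperm DNA of Wistar rat males of the parental generation was measured this way in 14 libraries of 4 groups: untreated controls (3 libraries), high-fat diet (HFD, 4 libraries), early-life stress by maternal separation (ELS, 4 libraries), and separation followed by high-fat diet (ELS-HFD, 3 libraries). Pups were separated from the dam for 3 h per day over 16 days from postnatal day 1, an elevated plus maze test followed at postnatal day 57, and the diets were split at postnatal day 60. The deposited tables hold 5 comparisons of these groups. They list 8555 candidate regions of at least 10 CpGs, each with the mean methylation of every library in percent, and 58 of the listed regions have a q-value under 0.05 in the authors' deposited table. Those 58 are named called regions here. They mark 48 separate loci, and methylation was lower in the first-named group in 48 of the 58 and higher in 10. Read depth per library and per CpG is unknown, so no interval for counting error can be given, and the SD over libraries is the only error available. The table codes for the groups are not spelled out in the labels. They were read as the 4 groups by their letters and by the number of libraries. Coordinates are those of the rat assembly Rnor_6.0, counted from 1.

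The comparison of HFD with control asks about the diet without separation. High-fat diet went with 10 called regions, 4 with higher and 6 with lower methylation, mostly at CpGs that were close to unmethylated in both groups. Values are means ± SD over 4 HFD and 3 control libraries. The largest decrease lay in intron 2 of Slc46a3, a lysosomal transporter gene (chromosome 12, 8729035 to 8729288), at 10.2 ± 12.1% against 24.6 ± 17.2%. LOC681410 (chromosome 17, 6910064 to 6910120, exon 1) had 0.325 ± 0.217% against 5.25 ± 1.44%, intron 1 of Cog1, a Golgi tethering subunit, 0.571 ± 0.101% against 3.79 ± 1.82%, and intron 1 of Rapgef6, an exchange factor for Rap GTPases, 0.284 ± 0.269% against 3.09 ± 0.757%. Exon 2 of the zinc finger gene Zfp503 stood at 0.343 ± 0.226% against 2.899 ± 0.999%. The increases were at exon 1 of Foxe1, a forkhead factor of thyroid development (chromosome 5, 61956104 to 61956170), with 7.47 ± 4.295% against 0.159 ± 0.275%, and in intron 2 of the imprinted Gnas locus, which encodes the stimulatory G protein alpha subunit (chromosome 3, 172418704 to 172418760), with 4.72 ± 0.7703% against 1.29 ± 0.979%. The promoters of Plxna2, a semaphorin receptor of axon guidance, and of Mcm3ap, a messenger RNA export factor, followed with 3.34 ± 2.49% against 0.399 ± 0.113% and 3.03 ± 1.97% against 0.662 ± 0.281%. A called region beside a 5.8S ribosomal RNA copy on chromosome 1 had 13.05 ± 10.1% against 15.9 ± 5.65%, in a sequence that has many copies, where reads of different copies cannot be separated here. The q-values of these regions in the authors' deposited table ran from 7.04e-06 to 0.0491. The groups' libraries did not overlap in 7 of these 10 regions and in 22.6% of the 1583 listed regions. Chance gives 5.71% only for regions not chosen for a difference, as all of these were. limma on the library values passed 0 of the 1583 listed regions after Benjamini-Hochberg adjustment, with 361 at an unadjusted p under 0.05 on the logit scale and 174 on the percent scale, where 0 passed. Without the control library at 4.89% the Slc46a3 difference was -24.3 percentage points and without the one at 35.98% it was -8.71, against -14.4 with all 7. The ribosomal difference of -2.82 became 0.395 without the control library at 22.3%, -7.85 without the HFD library at 28.1%, and -0.897, -1.27 and -1.28 without the HFD libraries at 7.27, 8.4005 and 8.41%, and -4.88 without the control library at 11.8%. The Mcm3ap difference of 2.36 became 1.38 without the HFD library at 5.98%.

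Maternal separation without the diet went with 17 called regions, 15 lower and 2 higher than control, most of them at partly methylated sites outside promoters. Values are means ± SD over 4 ELS and 3 control libraries. The largest decrease was intergenic (chromosome 10, 70015518 to 70015619; nearest gene AABR07072158.1), with 14.9 ± 8.86% against 50.9 ± 24.1%. Intron 6 of Sh3pxd2a, a podosome scaffold gene (chromosome 1, 267092836 to 267092912), had 35.8 ± 6.21% against 60.8 ± 11.3%. The Slc46a3 region had 5.49 ± 1.56% against 24.6 ± 17.1%. A site upstream of Fgf23, which encodes a phosphate-regulating hormone (chromosome 4, 159611771 to 159612033), had 26.5 ± 1.87% against 45.3 ± 12.1%, and intron 23 of transcript ENSRNOT00000091316 on chromosome 9, nearest to LOC689599, 22.2 ± 2.36% against 39.7 ± 10.1%. Intergenic sites near Hhat, the Hedgehog acyltransferase, and Fads1, a fatty acid desaturase, had 64.9 ± 3.11% against 79.2 ± 4.704% and 68.5 ± 2.77% against 80.2 ± 5.98%. The region upstream of Dpm3, a subunit of dolichol-phosphate mannose synthase (chromosome 2, 188578655 to 188578817), had 49.95 ± 4.62% against 63.7 ± 8.15%. The sites nearest to AABR07044988.3 and Btbd11 had 4.14 ± 2.25% against 15.5 ± 6.21% and 9.001 ± 4.72% against 19.4 ± 2.89%. The 2 increases were at exon 7 of transcript ENSRNOT00000073718 (chromosome 17, 87622506 to 87622922), whose nearest promoter of record is that of Arhgap21 at 203707 bp, with 79.9 ± 19.5% against 59.6 ± 7.71%, and at exon 1 of LOC100911196, next to AABR07002384.1, with 10.003 ± 5.02% against 1.06 ± 1.12%. At the Arhgap21 region the ELS libraries had 96.6, 96.0, 57.5 and 69.6%, and the control libraries 51.0, 66.0 and 61.7%. That increase thus rests mainly on 2 ELS libraries, and its limma p was 0.0691 before adjustment. Outside the naming rule, and named after their values were seen, exon 1 of Sod1, which encodes the copper-zinc superoxide dismutase (chromosome 11, 30363366 to 30363416), had 17.6 ± 1.91% against 27.4 ± 2.22% and Wipf3 80.8 ± 6.55% against 90.1 ± 1.26%, while LOC681410, Galnt7 and Crebrf differed at low levels. The q-values in the authors' deposited table ran from 3.13e-11 to 0.0341. The groups' libraries did not overlap in 15 of these 17 regions and in 25.7% of the 1849 listed regions. Chance gives 5.71% only for regions not chosen for a difference, as all of these were. limma on the library values passed 0 of the 1849 listed regions after Benjamini-Hochberg adjustment, with 497 at an unadjusted p under 0.05 on the logit scale and 304 on the percent scale, where 0 passed. Without the control library at 58.97% the Fgf23 difference was -11.9 percentage points against -18.8, without the one at 4.94% that of Slc46a3 was -28.95 against -19.1, and without the one at 5.24% that of Crebrf was -1.53 against -2.57.

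Separation followed by high-fat diet, set against control, gave 13 called regions, 11 lower and 2 higher. Values are means ± SD over 3 ELS-HFD and 3 control libraries. Decreases of the largest size were intergenic: near AABR07072158.1 7.64 ± 4.65% against 50.9 ± 24.1%, near AABR07009373.2 (chromosome 2, 94872583 to 94872909) 27.2 ± 14.6% against 63.05 ± 20.4%, and near AABR07068625.1 (chromosome 9, 112662906 to 112663198) 45.1 ± 16.3% against 73.9 ± 10.6%. The Dpm3 region had 37.4 ± 13.6% against 63.2 ± 7.62%, and intron 1 of Tm4sf20, a tetraspanin-like membrane protein gene (chromosome 9, 88528868 to 88529030), 46.6 ± 5.45% against 69.7 ± 1.41%. Exon 1 of Sod1 had 7.83 ± 8.67% against 29.3 ± 2.401%, exon 1 of Pheta1 (chromosome 12, 40226887 to 40227134) 29.4 ± 3.05% against 46.2 ± 12.04%, and the Btbd11 site 4.33 ± 4.99% against 19.4 ± 2.89%. Lower values at nearly unmethylated sites were found near Man2a1, a Golgi mannosidase, with 0.726 ± 0.684% against 4.86 ± 1.65%, and at the end of the Irgq transcript, with 1.29 ± 1.22% against 4.601 ± 1.83%. The promoter of RT1-CE5, a class I gene of the rat major histocompatibility complex (chromosome 20, 4897027 to 4897083), was higher, at 17.3 ± 6.82% against 0.432 ± 0.418%, and so was an intergenic site nearest to a 7SK small nuclear RNA copy, at 90.9 ± 0.873% against 83.4 ± 3.15%. RT1-CE5 belongs to a family of similar genes, so the member behind these reads is uncertain. Asmt, the last enzyme of melatonin synthesis, falls outside the naming rule as the 11th decrease. Its region lies in exon 5 of transcript ENSRNOT00000037829, upstream of the Asmt promoter, with 1.56 ± 0.583% against 4.79 ± 2.27%. The q-values in the authors' deposited table ran from 1.08e-09 to 0.0331. The groups' libraries did not overlap in 13 of these 13 regions and in 38.7% of the 1867 listed regions. Chance gives 10% only for regions not chosen for a difference, as all of these were. limma on the library values passed 2 of the 1867 listed regions after Benjamini-Hochberg adjustment, with 520 at an unadjusted p under 0.05 on the logit scale and 306 on the percent scale, where 0 passed. Past limma on the logit scale were RT1-CE5 and an exon near AC133265.1 on chromosome 8, which was not called and was named after its values were seen, with 0.5602 ± 0.0626% against 9.94 ± 1.06%. Their limma adjusted p-values were 0.0245 for AC133265.1 and for RT1-CE5 0.0306. Without the control library at 58.9% the Pheta1 difference was -10.5 percentage points against -16.8, and without the one at 7.41% that of Asmt was -1.92 against -3.23.

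Separation within the high-fat diet, ELS-HFD against HFD, gave 7 called regions, 6 of them lower. Values are means ± SD over 3 ELS-HFD and 4 HFD libraries. The Dpm3 region was lower here too, with 37.4 ± 13.6% against 59.01 ± 13.8%. Intron 9 of Disc1, a gene studied for its link with psychiatric illness (chromosome 19, 58002130 to 58002260; nearest promoter of record AABR07044106.1), had 8.298 ± 2.42% against 33.03 ± 17.3%. A region in intron 1 of transcript ENSRNOT00000020272 on chromosome 1, with an RNase P RNA copy as its nearest gene at 16498 bp, had 37.6 ± 13.6% against 59.9 ± 8.51%, and a site nearest to AABR07007717.1 on chromosome 2 8.197 ± 2.03% against 16.4 ± 3.88%. The Gnas intron 2 region (chromosome 3, 172418745 to 172418790) had 0.853 ± 0.808% against 4.76 ± 1.24%, and the promoter of the signalling adaptor gene Traf6 0.456 ± 0.178% against 3.17 ± 2.37%. Exon 1 of Pcdhgc3, of the gamma protocadherin cluster of similar genes (chromosome 18, 30914510 to 30914576), was higher, at 7.16 ± 2.81% against 0.5 ± 1%. The q-values in the authors' deposited table ran from 6.43e-06 to 0.0487. The groups' libraries did not overlap in 5 of these 7 regions and in 23.9% of the 1653 listed regions. Chance gives 5.71% only for regions not chosen for a difference, as all of these were. limma on the library values passed 0 of the 1653 listed regions after Benjamini-Hochberg adjustment, with 416 at an unadjusted p under 0.05 on the logit scale and 217 on the percent scale, where 0 passed. Without the HFD library at 6.33% the Traf6 difference was -1.66 percentage points against -2.71, and without the ELS-HFD library at 22.1% that of the region nearest to the RNase P copy was -14.4 against -22.2.

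High-fat diet in separated males, ELS-HFD against ELS, gave 11 called regions, 10 of them lower. Values are means ± SD over 3 ELS-HFD and 4 ELS libraries. The exon 7 region assigned to Arhgap21 had 59.8 ± 10.9% against 78.4 ± 18.2%, and the exon 1 region of LOC100911196 next to AABR07002384.1 2.05 ± 0.727% against 10.6 ± 4.02%. At the Arhgap21 region the limma p was 0.0723 before adjustment. An intergenic site near AABR07054752.1 (chromosome 3, 168590048 to 168590287) had 15.9 ± 6.13% against 30.9 ± 7.88%. A region at a transcript end near Zfp219 (chromosome 15, 28402901 to 28403235) had 11.5 ± 2.42% against 26.7 ± 9.71%. Lower values at nearly unmethylated sites were found near Dlg5, a scaffold protein gene, with 2.14 ± 0.808% against 7.26 ± 1.17%, at RGD1560108 with 0.548 ± 0.371% against 5.49 ± 3.91%, and near Mir6334 with 1.09 ± 0.869% against 5.31 ± 2.37%. A region assigned to Grin3b, an NMDA receptor subunit gene (chromosome 7, 12770985 to 12771055), lay 6027 bp from its start at the end of another transcript and had 2.23 ± 1.04% against 6.71 ± 3.88%. The region assigned to Grn, the progranulin gene, lay in exon 8 of Fam171a2, with 1.43 ± 0.612% against 4.45 ± 2.09%. Intron 19 of transcript ENSRNOT00000046802 (chromosome 5, 156068848 to 156069014), nearest to the Alpl promoter, was higher, at 76.6 ± 16.98% against 65.5 ± 7.16%. The q-values in the authors' deposited table ran from 1.23e-07 to 0.0434. The groups' libraries did not overlap in 7 of these 11 regions and in 24.1% of the 1603 listed regions. Chance gives 5.71% only for regions not chosen for a difference, as all of these were. limma on the library values passed 0 of the 1603 listed regions after Benjamini-Hochberg adjustment, with 437 at an unadjusted p under 0.05 on the logit scale and 222 on the percent scale, where 0 passed. The Alpl difference of 11.1 percentage points was 20.7 without the ELS-HFD library at 57.3% and 4.74 without the one at 89.3%.

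Of the 48 loci, 9 were called in at least 2 comparisons. Dpm3 was lower in ELS and in ELS-HFD than in control, and lower in ELS-HFD than in HFD: its group means were 63.2 ± 7.62% in control, 59.01 ± 13.8% in HFD, 49.95 ± 4.62% in ELS (over an interval that ends at 188578817, the others at 188578842) and 37.4 ± 13.6% in ELS-HFD. Sod1, Btbd11 and the AABR07072158.1 site were lower than control in both separated groups. Slc46a3 and LOC681410 were lower than control in HFD and in ELS. Gnas was higher in HFD than in control and lower in ELS-HFD than in HFD. The Arhgap21 and AABR07002384.1 regions were higher in ELS than in control and lower in ELS-HFD than in ELS. Both calls at Gnas use the same 4 HFD libraries, and both at the other 2 the same 4 ELS libraries. Simulated groups with no effect moved the same way at only 6.27% and 6.29% of overlapping regions in these 2 pairs of comparisons (17.3% and 22.5% in the tables), so opposite directions are expected there without an effect. No gene was called in all 3 comparisons against control. ELS and ELS-HFD shared 4 called genes against control, all lower, where independent lists of these sizes among 3797 genes give 0.0435 shared lower genes. HFD and ELS shared 2 lower genes, where independent lists give 0.0237. These comparisons use the same 3 control libraries, too few to split, so part of that excess may come from them and it is not a measure of a shared effect. Among all listed regions that overlap, 83.7% moved the same way for HFD and ELS, 83.97% for HFD and ELS-HFD and 92.99% for ELS and ELS-HFD. Simulated groups with no effect against shared controls gave 98.2%, 96.97% and 96.97%, so a high share can arise here without an effect in common. All simulated regions had the same SD, while SDs of real regions vary widely, so the simulated shares are no exact reference for the real ones.

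**Figure D1:**
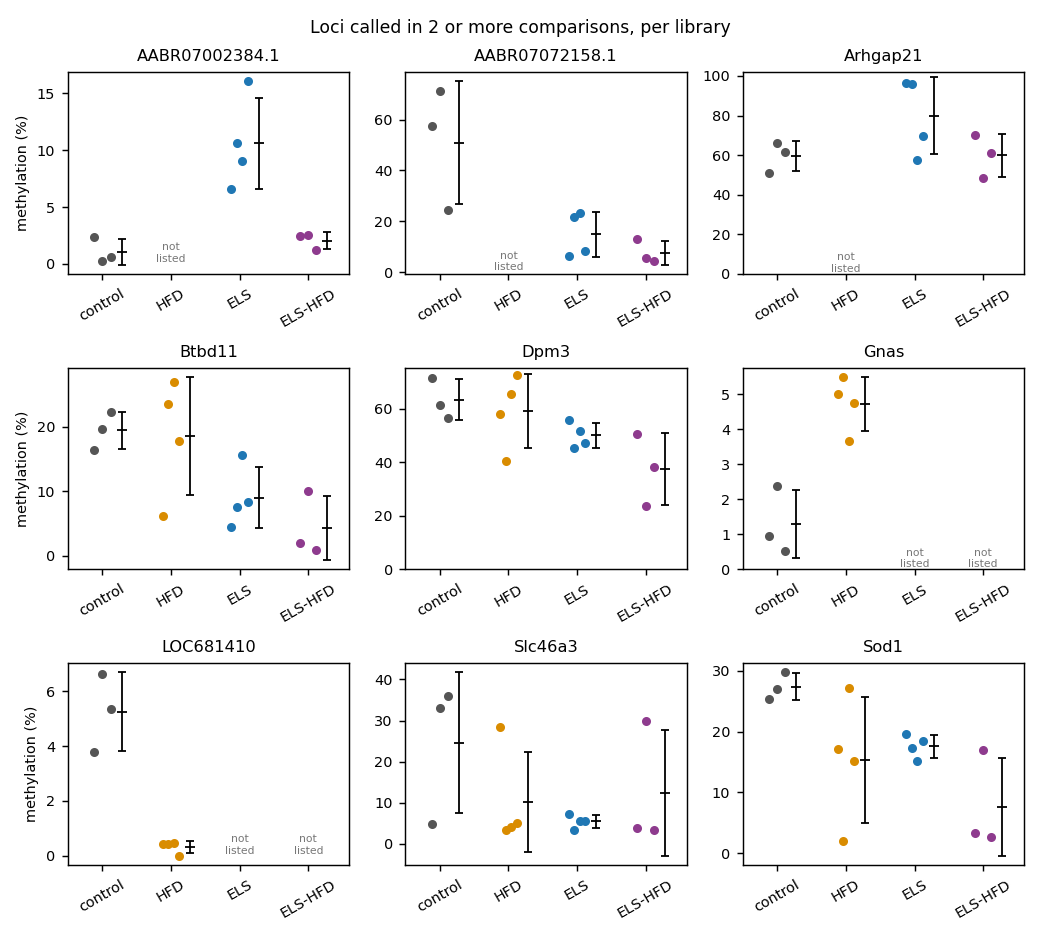
Methylation in percent (y axis) of each library by group (x axis) at the 9 loci called in 2 or more comparisons; points are libraries and bars beside them the mean ± SD. At Dpm3 the group means run from 63.2% in control to 37.4% in ELS-HFD, and at Slc46a3 the libraries sit at 2 levels; "not listed" marks groups with no value over the interval drawn, as at Gnas and LOC681410, whose other call covers a shifted interval.

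There are 2 pairs of comparisons that share no library and ask about 1 factor each. The separation difference was measured in chow-fed males (ELS against control) and in males on high-fat diet (ELS-HFD against HFD). At 463 pairs of listed regions that overlap by at least 1 bp, 322 (69.5%) moved the same way in both diets, 246 lower and 76 higher in the separated groups. The shares of higher regions in each table alone would give 56.7% (Fisher's exact test, two-sided, p = 4.24e-10 over regions, which are not independent replicates). The diet difference, measured without separation (HFD against control) and with it (ELS-HFD against ELS), moved the same way at 207 of 376 pairs (55.1%, where the tables alone give 49.7%; Fisher's exact test, two-sided, p = 0.0379 over regions). With the diet label shuffled among the unseparated and among the separated libraries, 19 of 100 splits gave a share as large as the real one (55.3% from the library values, highest other 63.03%), so chance cannot be excluded for the diet share. With an overlap of at least 50% of both regions the diet share was 52.3% (exact p = 0.457), and it also missed the threshold without HFD library 2 or 3, control library 1 or 2, ELS-HFD library 1, or ELS library 1, 2 or 3 (numbered by column), at 53.5 to 54.8%. Among called regions, 1 locus was called in both separation tables, Dpm3, lower in both, and 0 in both diet tables. At exon 1 of Sod1 the 4 group means were 27.4 ± 2.22% in control, 15.4 ± 10.4% in HFD, 17.6 ± 1.91% in ELS and 7.64 ± 8.05% in ELS-HFD over 1 interval. At the Disc1 intron the control and ELS means, 36.5 ± 34.6% and 11.7 ± 6.43%, end at 58002249, and those of HFD and ELS-HFD, 33.03 ± 17.3% and 8.298 ± 2.42%, at 58002260. Without the control library at 76.2% the ELS difference there was -4.85 percentage points against -24.7, so most of it rests on 1 library.

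A 2 x 2 fit with limma tested both factors and their interaction at 499 regions that have values of all 14 libraries. After Benjamini-Hochberg adjustment 3 regions passed for separation, 3 for diet and 0 for the interaction, with 121, 69 and 63 at an unadjusted p under 0.05. Those for separation were Patz1 (higher in separated males), Rhobtb1 and Cbx6 (lower), and those for diet U6 and H6pd (higher on high-fat diet) and Lrrc8d (lower), all named after their values were seen. The groups of a region come from 2 tables whose intervals can differ, and they differ at all 6. At Patz1, U6, H6pd and Lrrc8d that difference falls on the factor for which they passed, so it cannot be separated from the factor there. Among the 162 regions with identical coordinates in both tables, limma passed 0 for separation, diet and the interaction (29, 16 and 16 at an unadjusted p under 0.05). Over the 306 regions where separation is compared within a table, limma passed 14 for separation, among them Cbx6, Rhobtb1 and the called loci Btbd11, LOC689599 and AABR07007717.1, but these regions were listed for that same difference. In the fit of all 499 regions Disc1, Sod1 and Dpm3 did not pass, with limma adjusted p for separation of 0.105, 0.255 and 0.0945. These regions were listed because the groups differed, so the adjusted p-values are too small. The count for separation was 0 without control library 3, ELS-HFD library 3 or ELS library 2, 3 or 4, 5 without HFD library 3, 6 without ELS-HFD library 1 and 7 without HFD library 2. The count for diet was 1 without control library 2 or 3 or without any 1 of the 3 ELS-HFD libraries, and the interaction count was 1 without HFD library 4.

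**Figure D2:**
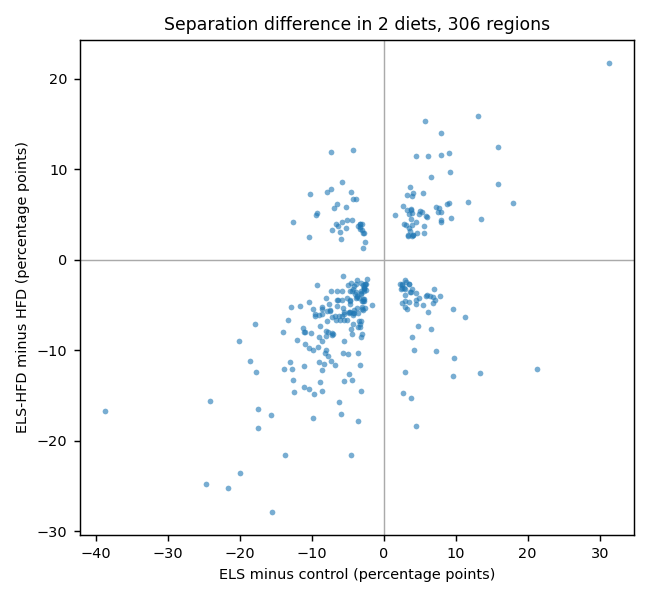
Difference in methylation between separated and unseparated males in percentage points, in chow-fed males (x axis, ELS minus control) and in males on high-fat diet (y axis, ELS-HFD minus HFD), for 306 regions that overlap by at least 50% between the 2 tables; each point is a region. Points in the lower left and upper right moved the same way in both diets.

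Over all listed regions, called or not, the direction differed between the comparisons. ELS-HFD was lower in 69.95% of the 1867 regions listed against control, 73.8% of the 1653 against HFD and 61.9% of the 1603 against ELS. ELS was lower than control in 60.95% of 1849 regions, and HFD in 43.7% of 1583. Averaged over the regions listed against control, ELS-HFD library 2 (by column) had 25.4%, the other ELS-HFD libraries 28.0 and 27.8%, and control 28.9 to 29.8%. It was also the lowest ELS-HFD library against HFD and against ELS. In ELS against control, ELS library 2 averaged 29.4% and the other ELS libraries 31.1 to 32.5%. The regions were listed with all libraries, so the part of a single library in these shares cannot be told. Among regions whose libraries averaged under 10%, ELS-HFD was lower in 74.1%, 78.6% and 74.7% of regions against control, HFD and ELS (Wilson 95% intervals 71.1 to 76.98%, 75.6 to 81.2% and 71.3 to 77.8%, for the counting of regions only). These 3 comparisons use the same 3 ELS-HFD libraries and are not separate observations. Against ELS the direction turned at higher levels: 42.6% of 284 regions between 50 and 90% were lower in ELS-HFD, and 31.2% of 128 regions at 90% or more. ELS against control differed in this, with 51.4% of regions lower under 10% and 75.2% lower between 50 and 90%. That comparison and ELS-HFD against ELS use the same ELS libraries with opposite sign. Their patterns at higher levels are therefore not separate observations.

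**Figure D3:**
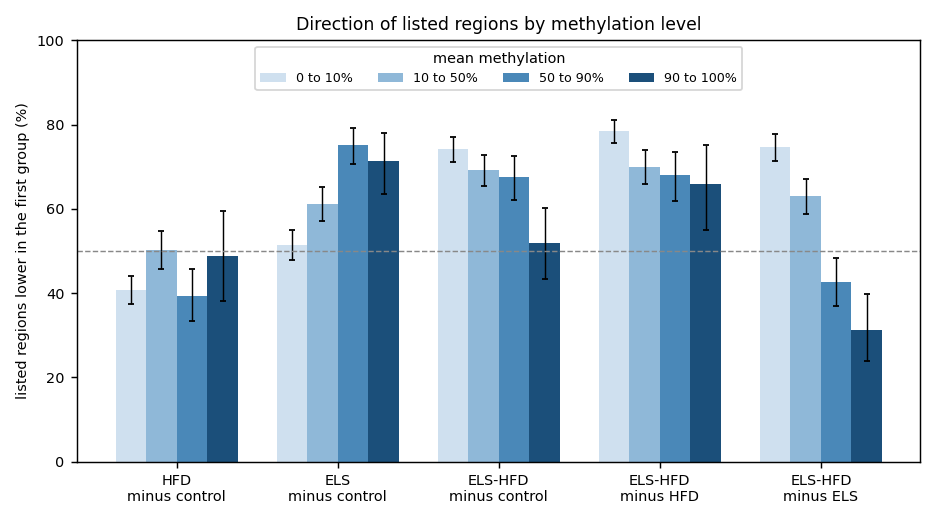
Share of listed regions in percent (y axis) with lower methylation in the first-named group, for the 5 comparisons (x axis) and 4 ranges of mean methylation over the libraries compared (bar shades); error bars are Wilson 95% intervals for counting regions and the dashed line marks 50%. In the range under 10% the 3 ELS-HFD comparisons stand at 74.1, 78.6 and 74.7%.

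Most listed regions lay outside promoters. Promoters held 16.6% of the regions of HFD against control (Wilson 95% interval 14.8 to 18.5%), 13.1% for ELS, 14.5% for ELS-HFD, and 16.3% and 10.8% for ELS-HFD against HFD and against ELS. Regions that were higher in HFD than in control lay in promoters more often than lower ones, 18.9% against 13.5% (Fisher's exact test, two-sided, adjusted p = 0.0206 over 25 tests), and in introns less often, 16.5% against 23.4% (adjusted p = 0.00463). In ELS against control the promoter shares were 9.97% of higher and 15.1% of lower regions (Fisher's exact test, adjusted p = 0.00904), and in ELS-HFD against ELS 14.7% and 8.37% (adjusted p = 0.00177). Both comparisons use the same ELS libraries with opposite sign. Simulated groups with no effect moved the same way at only 6.29% of their overlapping regions, so opposite promoter shares can arise there without an effect. Intergenic sites held 44.7% of higher and 35.8% of lower regions in ELS against control (Fisher's exact test, adjusted p = 0.00177), and exons 22.1% and 27.9% in ELS-HFD against ELS (adjusted p = 0.0402). The other 19 of the 25 tests did not pass. All these context tests run over listed regions, which come from the same few libraries and are not independent replicates. Their p-values therefore do not measure the spread between animals. Of the 58 called regions 4 lay in promoters, those of Plxna2, Mcm3ap, RT1-CE5 and Traf6, and 0 of 25 tests of context passed among called regions.

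The 12 gene lists fixed before the data were examined held 758 genes, of which 186 are named in any table. Only 3 of these have a called region: Gnas among imprinted genes, Plxna2 in axon guidance and Grin3b in the glutamate synapse. None of 60 list tests passed (Fisher's exact test, two-sided, smallest adjusted p = 0.859, with 2 at an unadjusted p under 0.05, both for Gnas). Adjusted over the list alone, 187 of the 462 regions listed for these genes pass on the authors' deposited 2-dimensional Kolmogorov-Smirnov p. That test runs over CpGs and over regions already chosen for their difference, so the count says nothing about the spread between animals. The values that follow are means ± SD over the libraries of each group (n = 3 or 4), for members without a called region, and do not mark a change. Of these members, the libraries of the 2 groups did not overlap at Grb10, Ngfr, Tsc22d3, Irs1, Gabrr1, Kcnn3, Pax2, Sox10, Tbx3, Tcf7l2, Apc2, Meioc and Dazl, each picked for a large difference. Some values are of intergenic sites that carry the gene of the nearest promoter, not of the gene itself. With the distance to its start in bp, these are Dkk2 (-67409), Tbx4 (31781), Htr1d (-29630), Ntrk2 (-21926), Ephb3 (20231), Ngfr (-10694), Kcnn3 (-8421), Sema6b (-5282), Htr3a (-4874) and Gad1 (-2977). Slc6a4, Piwil1 and Tex15 are marked as such below.

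Of 11 imprinted genes in the tables, 1 had a called region, Gnas, in HFD against control (Fisher's exact p = 0.0286) and in ELS-HFD against HFD (exact p = 0.0201), both with an adjusted p of 0.859. A region assigned to Zrsr1 had 23.9 ± 8.71% in ELS-HFD and 16.5 ± 7.36% in control. It lay -57624 bp from the Zrsr1 start, in intron 2 of transcript ENSRNOT00000012750, so it is not a value of Zrsr1 itself. The promoter of Igf2r, the insulin-like growth factor 2 receptor, had 6.73 ± 6.58% against 0.183 ± 0.317% in ELS-HFD and control. Grb10 had 5.68 ± 3.95% in ELS-HFD and 1.103 ± 0.479% in HFD at its promoter, and Dlk1 had 13.4 ± 7.97% in ELS-HFD and 18.3 ± 4.01% in HFD. Of 12 genes of the stress hormone axis and stress peptides 0 had a called region. Ngfr had 29.04 ± 5.26% in ELS-HFD and 14.2 ± 2.89% in control, Ntrk2 had 22.9 ± 3.45% in ELS-HFD and 30.99 ± 7.32% in control, and Sgk1 had 11.99 ± 5.47% in ELS-HFD and 17.7 ± 10.4% in HFD. On the X chromosome, Tsc22d3 had 77.02 ± 0.288% in ELS-HFD and 72.1 ± 3.07% in control. Of 18 genes of energy balance, insulin and lipid metabolism 0 had one. Exon 1 of the insulin receptor substrate gene Irs1 had 16.4 ± 3.67% against 6.45 ± 2.24% in ELS and control, and Acacb had 23.9 ± 14.2% in ELS-HFD and 15.3 ± 4.89% in control.

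In the glutamate synapse list 1 of 18 genes had a called region, Grin3b. Its members with an unadjusted Kolmogorov-Smirnov p under 0.05 in the authors' deposited table numbered 8 in ELS-HFD against HFD, all lower in ELS-HFD, against 3.46 from the background (Fisher's exact p = 0.0127, adjusted p = 0.649). Of all regions under that threshold in this comparison 77.1% were lower. Shank2 had 66.2 ± 8.55% in ELS and 78.2 ± 12.99% in control, Grik3 had 68.2 ± 11.8% in ELS and 79.7 ± 5.87% in control, Shank3 had 19.7 ± 4.19% in HFD and 12.1 ± 2.41% in control and Grin2d had 24.3 ± 3.92% in ELS-HFD and 31.6 ± 2.67% in ELS. Axon guidance had 1 of 27 genes called, Plxna2. Ephb1 had 41.6 ± 17.98% in HFD and 23.7 ± 14.8% in control, Sema3g had 45.2 ± 13.5% in ELS-HFD and 29.9 ± 8.72% in HFD, Sema6b had 45.7 ± 7.99% in ELS and 54.8 ± 5.97% in control and Ephb3 had 29.1 ± 16.03% in ELS-HFD and 37.9 ± 12.9% in control. The remaining neuronal lists had 0 called genes: 4 of the GABA and glycine synapse, 4 of monoamine signalling and 12 voltage-gated calcium and potassium channels are named in the tables. The glutamate decarboxylase gene Gad1 had 1.14 ± 0.7898% in HFD and 4.36 ± 2.63% in control, and Gabrr1 had 6.18 ± 0.546% in ELS and 3.17 ± 1.198% in control. Slc12a5 had 1.01 ± 0.859% in ELS-HFD and 4.51 ± 4.46% in control. Htr3a had 25.8 ± 4.81% in HFD and 17.7 ± 3.303% in control, Htr1d had 7.402 ± 1.05% in ELS-HFD and 13.6 ± 6.64% in control and Slc6a2 had 3.13 ± 2.94% in HFD and 0.521 ± 0.585% in control. An intergenic site at -10013 bp from the start of the serotonin transporter gene Slc6a4 was listed at 0 in all 3 ELS-HFD libraries, with 5.21 ± 6.395% in HFD. Cacna1i had 31.1 ± 12.7% in ELS-HFD and 18.5 ± 6.68% in control, Kcnn3 had 7.77 ± 2.79% in ELS-HFD and 16.2 ± 2.38% in HFD and Cacna1g had 42.4 ± 4.25% in ELS-HFD and 33.9 ± 7.62% in ELS.

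Among 45 homeobox and other patterning transcription factors 0 had a called region, and 15 passed the unadjusted Kolmogorov-Smirnov threshold in ELS-HFD against HFD where 8.65 were expected (Fisher's exact p = 0.0216, adjusted p = 0.649). Exon 3 of Pax2 had 52.3 ± 10.7% against 35.1 ± 3.24% in ELS-HFD and control, the Sox10 promoter 82.5 ± 5.36% against 70.5 ± 2.88% in the same groups. Tbx3 had 36.2 ± 5.37% in ELS-HFD and 48.8 ± 6.21% in HFD, and Tbx4 had 52.4 ± 20.5% in ELS and 40.3 ± 10.2% in control. Of 16 Wnt signalling genes 0 were called. Wnt11 had 19.6 ± 4.91% in ELS-HFD and 31.97 ± 11.6% in HFD, Tcf7l2 had 6.08 ± 2.55% in ELS-HFD and 15.05 ± 1.75% in control, Dkk2 had 58.3 ± 11.9% in ELS-HFD and 65.3 ± 3.13% in control and Apc2 had 14.8 ± 0.698% in ELS-HFD and 20.5 ± 6.41% in HFD. Of 11 genes of the DNA and histone methylation machinery 0 were called. Setd7 had 85.2 ± 2.45% in HFD and 77.03 ± 8.798% in control, Kdm1b had 87.8 ± 9.44% in ELS-HFD and 93.6 ± 5.07% in ELS, Dnmt3l had 86.5 ± 2.97% in ELS-HFD and 91.7 ± 2.24% in ELS and Kdm5a had 0.812 ± 0.741% in ELS-HFD and 4.74 ± 5.37% in control. The list of germline genes whose promoters are methylated in somatic cells, a marker of somatic DNA in a sperm sample, had 0 of 11 genes called. Meioc had 1.32 ± 0.948% in ELS-HFD and 6.45 ± 2.94% in control, and Dazl had 6.13 ± 1.89% in ELS and 2.02 ± 0.211% in control. Piwil1 had 80.1 ± 16.01% in ELS-HFD and 95.04 ± 1.99% in ELS, and Tex15 had 18.6 ± 4.94% in ELS-HFD and 24.1 ± 4.44% in HFD, at sites far from their promoters. Regions within 1000 bp of a germline gene start were listed 12 times for 6 genes, and the highest library there had 12.5%. All 7 of these that involve ELS-HFD were lower in ELS-HFD, at Meioc, Sohlh2, Topaz1 and Dazl. They are not independent, since the Sohlh2 site is listed in each ELS-HFD comparison, with the same ELS-HFD libraries.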

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

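Of the tests in this part, those of a variant at 1 CpG and of a single mislabelled library were chosen after the values were seen. At called regions, 45 groups of 4 libraries were examined for a library far from the others. In 6 of them its gap to the nearest other library, divided by the range of the group, was above Dixon's 95% critical value for 4 samples, where chance gives about 1 in 20, or 2.25. At members of the gene lists this held for 2 of 30 groups, where chance gives 1.5, and 1 of the 2 is described here. All 6 at called regions were in the HFD group. Only HFD and ELS have 4 libraries, so control and ELS-HFD were not examined, and the flags do not rank HFD against them. Those at LOC681410 and Pcdhgc3 are among values of 2% or less.

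The HFD library at 28.3% in intron 2 of Slc46a3 stood apart from the others at 3.39 to 5.05% (ratio 0.933). Over all 14 libraries this region had 2 levels, 28.3 to 35.9% in 4 libraries (2 of 3 control, 1 of 4 HFD, 0 of 4 ELS and 1 of 3 ELS-HFD) and 3.27 to 7.27% in the other 10. A variant at 1 CpG could shift the mean by at most 2.78 percentage points, while the levels lay 21.1 apart, which argues against it. The HFD library at the high level lay nearer to the control mean in 0 of the 9 other regions called in HFD against control, but these were called with its label, so mislabelling stays open, though a single mislabelled library as the only reason is argued against: 3 of 14 libraries need another label for each group to have 1 level. A difference over the whole region that rats inherit, or litter, may underlie the 2 levels and stays open as untested. Both levels occurred in 3 of the 4 groups, control, HFD and ELS-HFD, which argues against diet or separation alone setting the level. Whether diet or separation has a part in it stays open as untested.

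Near the 5.8S ribosomal RNA copy an HFD library had 28.1%, the others 7.27 to 8.41% (ratio 0.946). At LOC681410 an HFD library was listed at 0, the others at 0.413 to 0.455% (ratio 0.909). At the Mcm3ap promoter an HFD library had 5.98%, the others 1.93 to 2.10% (ratio 0.957). At Pcdhgc3 an HFD library had 2%, while the other 3 were listed at 0 (ratio 1). At the Disc1 intron region (AABR07044106.1) an HFD library had 7.40%, the others 38.6 to 44.4% (ratio 0.842). At Apc2 an HFD library had 29.999%, the others 16.2 to 18.4% (ratio 0.839). Numbered by column, HFD library 1 was the one apart at Slc46a3, Mcm3ap and the Disc1 intron. It was HFD library 2 near the 5.8S copy and at Pcdhgc3, and HFD library 4 at LOC681410. The flags at called regions are thus not all from separate libraries.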

How the results depend on the processing

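The limma fits, the condition that libraries do not overlap, the same-direction shares of listed regions, the shares of lower regions, the Kolmogorov-Smirnov threshold and the RefSeq background for the lists, shared loci without the sex chromosomes, and the 2 x 2 fit with its alternatives were chosen after the data were seen. No paired analysis was possible because the labels give no litter or other pairing of libraries between groups. The table columns also carry no replicate numbers. Depth is not given, so no coverage minimum could be tried and what depth limits is unknown. The background of genes with simulated restriction fragments was not run, since no genome of this build was used here, and a minimum of 10 CpGs removed no region. With the q-value of the authors' deposited table under 0.01, called regions numbered 11 in ELS against control, 3 in ELS-HFD against HFD and 5 in ELS-HFD against ELS, fewer by construction. With a difference of at least 20 percentage points they numbered 0, 3 and 6 for HFD, ELS and ELS-HFD against control and 3 and 0 for ELS-HFD against HFD and against ELS, loci called in 2 or more comparisons numbered 2, and separation loci called in both diets 0. limma passed 0, 0, 2, 0 and 0 regions on the logit scale (361, 497, 520, 416 and 437 at an unadjusted p under 0.05) and 0 in all 5 comparisons on the percent scale (174, 304, 306, 217 and 222). Of 11 called regions of ELS-HFD against ELS, 7 had libraries that do not overlap. The difference in promoter share between higher and lower regions no longer passed among regions with a q-value under 0.01 in the authors' deposited table (50 percentage points for HFD and 0 for ELS against control) or with a difference of at least 20 percentage points (0 and -12.5), which leave few regions. The share of diet pairs moving the same way was 52.3% with an overlap of at least 50% and 53.5 to 56.1% without 1 library, with exact p-values of 0.0167 to 0.141; the cause was not tested. The share of separation pairs was 100% (3 pairs) with a difference of at least 20 percentage points and 67.6 to 70.2% without 1 library. The share of lower regions with that difference was 50% for HFD and 72.7% for ELS against control, 81.8% for ELS-HFD against HFD and 0% (4 regions, reversed) for ELS-HFD against ELS. At an unadjusted Kolmogorov-Smirnov p under 0.05 it was 47.7% for HFD and 74.4% for ELS-HFD against control, and 77.1% and 64.9% for ELS-HFD against HFD and against ELS; the cause was not tested. Without 1 library, the difference near the 5.8S ribosomal RNA ran from -7.85 to 0.395 percentage points, the only 1 of 58 called regions to reverse. The 2 x 2 limma counts ran from 0 to 7 for separation, 1 to 4 for diet and 0 to 1 for the interaction without 1 library, and the cause was not tested. Only with the 162 regions of identical coordinates in both tables they were 0, 0 and 0, and over regions where the factor is compared within a table they were, for separation, 14 (306 regions) and for diet 0 (193 regions). Without 1 library, the called regions that kept their direction and a difference of at least 2.5 percentage points numbered 7 to 9 of 10 for HFD, 16 to 17 of 17 for ELS and 12 to 13 of 13 for ELS-HFD against control, 6 to 7 of 7 for ELS-HFD against HFD and 10 to 11 of 11 for ELS-HFD against ELS. The list tests passed 0 times under each of their alternatives, with a smallest adjusted p of 0.364 (Fisher's exact test, all protein-coding RefSeq symbols as background). Leaving out the sex chromosomes changed no count of called regions.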

Other observations

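Among the tests in this part, the 2 x 2 fit, its relabellings and its repeats on fewer regions, the splits of limma, the same-direction shares of listed regions, the shares of lower regions, and the leave-one-out, germline and single-group conversion tests of the low-methylation pattern were chosen after the result was seen. The 6 regions past the 2 x 2 limma fit were also named after their values were seen, the coordinates are those of the first table, and values are means ± SD over 3 control, 4 HFD, 4 ELS and 3 ELS-HFD libraries. Exon 5 of Cbx6, which encodes a Polycomb protein (chromosome 7, 121052855 to 121053038), had 63.6 ± 5.04% in control and 55.0 ± 5.38% in HFD, and 41.9 ± 9.83% in ELS and 29.8 ± 10.7% in ELS-HFD. Exon 7 of Rhobtb1 (chromosome 20, 20658303 to 20658880), had 15.3 ± 2.57% and 19.3 ± 3.88%, and 10.4 ± 0.900% and 6.70 ± 3.09% in the same order. Intron 1 of the zinc finger gene Patz1 (chromosome 14, 83511790 to 83512155) was higher in separated males, with 17.1 ± 3.31% and 14.3 ± 1.87% against 30.1 ± 2.92% and 25.6 ± 3.31%. All 3 had a limma adjusted p of 0.0264 for separation. For diet, an intergenic site on chromosome 14 (5202794 to 5202976), with Lrrc8d as the gene of the nearest promoter, had 71.0 ± 5.56% in control and 74.3 ± 0.980% in ELS, and 53.3 ± 4.80% in HFD and 55.9 ± 0.838% in ELS-HFD (limma adjusted p = 0.00901). An intergenic site on chromosome 14 (84830898 to 84831300), nearest to a U6 copy, had 10.3 ± 1.29% and 8.67 ± 3.03%, and 22.3 ± 4.05% and 17.3 ± 1.13% in the same order (limma adjusted p = 0.0203). Exon 5 of H6pd, a sugar phosphate dehydrogenase of the endoplasmic reticulum (chromosome 5, 166999121 to 166999220), had 14.3 ± 4.20% and 11.5 ± 0.901%, and 24.1 ± 2.98% and 21.0 ± 0.645% (limma adjusted p = 0.0245). Without 1 library in turn, Lrrc8d passed in 14 of 14 fits, U6 and Patz1 in 9, Cbx6 in 7, Rhobtb1 in 6 and H6pd in 5. The 2 tables give different intervals at all 6, which falls on the factor tested at Patz1, Lrrc8d, U6 and H6pd, so the interval cannot be told apart from the factor there. At Cbx6 and Rhobtb1 separation is compared within each table. With only the 162 regions of identical coordinates limma passed 0 for each term (29 for separation, 16 for diet and 16 for the interaction unadjusted). Over the 306 regions where separation is compared within a table it passed 14 for separation, and over the 193 where diet is, 0 for diet (103 and 36 unadjusted), but these were listed for that same difference.

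At 19 called loci all 4 groups have values in the tables. The 4 groups cover the same interval at 10 of them, and intervals that differ at the other 9, where the order of the groups is less certain. Both separated groups were below both unseparated groups at 13 of the 19, among them Btbd11, Fads1 and Hhat with 1 interval, and above at 0, and below at 7 of the 10. The HFD groups were both lower at 2 loci, Sod1 and Zfp219 (the latter with different intervals), and both higher at 1, Alpl. The loci were called for differences in these same groups, so these counts describe them and test nothing. At the LOC689599 site on chromosome 9, where the tables give starts of 114896957 (control and ELS) and 114897077 (HFD and ELS-HFD), the 7 separated libraries had 23.4 ± 3.47% and the 7 others 40.6 ± 9.78%, with the highest separated library at 30.2% and the lowest other at 28.7%.

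The separation difference went the same way in both diets at 69.5% of 463 pairs of listed regions. With the separated label shuffled within each diet, 1 of 100 such splits, the real 1, gave a share as large (69.8% from the library values, highest other 65.2%), but the regions were listed for the real labels, so this does not exclude chance. The lowest share with 1 library left out was 67.6%. The regions were listed with all libraries, and few reversed without 1 or another library (7.14% for ELS against control, 8.65% for ELS-HFD against HFD). This test therefore cannot exclude a single library. A variant at 1 CpG is argued against only at the 66 pairs beyond what 1 CpG can shift. Of these 84.8% went the same way, where the tables alone give 74.2% (Fisher's exact test, two-sided, p = 0.00460). At the other 397 pairs 67.0% went the same way, where the tables alone give 54.8%, and a variant at 1 CpG stays open there. Litter or other inherited differences that go with the separated animals cannot be told apart from separation, since 0 columns of the labels name a litter. Separation itself may lie behind this, as a hypothesis.

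Listed regions under 10% methylation were mostly lower in ELS-HFD than in each other group, in 3 comparisons that share the same 3 ELS-HFD libraries and are not separate observations. The lowest share with 1 library left out was 72.9%. The regions were listed with all libraries, and few reversed without 1 or another library (8.36% of all regions listed against control, 8.65% against HFD, 9.17% against ELS). This test therefore cannot exclude a single library. Incomplete bisulfite conversion in the other groups would raise their lowest values, but 11.3% of their 2353 means in these regions lay below 1%. This argues against a floor raised by at least 2.5 percentage points in all 3, and in control (12.6%) and ELS (12.3%) alone. HFD, at 9.28%, is under the 10% bound set for this and stays open. A smaller rise stays open in every group. With listed differences of at least 2.5 percentage points, means below 1% lie mainly where ELS-HFD was higher. They hardly cover the regions that were lower. Less DNA from somatic cells in ELS-HFD cannot be told apart from the skew, since 7 regions near germline gene starts, from 4 genes, are too few: all 7 were lower, and even so the one-sided binomial exact test gives p = 0.134. That test counts the 7 as independent, so its p is too small. The Sohlh2 site enters in all 3 comparisons, with the same 3 ELS-HFD libraries. Less somatic DNA may be a source of the pattern, and separation with high-fat diet stays open, as untested.

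limma passed 0 regions in 4 comparisons, with at most 1 in another split, and 35 of 35 splits give at least 0 in any case, so this count tests nothing. Unadjusted counts were 361 for HFD and 497 for ELS against control, and 416 and 437 for ELS-HFD against HFD and against ELS, and the percent scale passed 0 in each (174, 304, 217 and 222 unadjusted). In ELS-HFD against control it passed 2, with 0 in the highest of the other splits (1 of 10 splits as large), and 10 splits are too few for a share under 0.05. In the 2 x 2 fit, 2 of 100 relabellings (splits of the 14 libraries) gave as many regions as the 3 for separation (highest other 3), 1 of 100 as many as the 3 for diet (highest other 2), and 100 of 100 as many as the 0 for the interaction (63 unadjusted, 0 on the percent scale, highest other 2), which tests nothing. The regions of that fit were listed for the real labels, so the counts for separation and diet do not exclude chance.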
